A study of Homo sapiens with 4 samples.

How the data were processed

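Per the labels' protocols, HCT116 cells were treated with 7A or DMSO for 24 h, total RNA was taken with a RNeasy kit, and 1.4 µg of it per sample went into a dual-mode mRNA library kit; the dose of 7A is not given in the sources used here. There are 4 samples, 2 per group. The deposited table holds raw counts per gene, a unit read from the name of the deposited table and from its values, which are whole numbers with unequal library totals. The submitters' processing notes name the builds hg38, mm10 and GRCm38 together. As for the species, every gene identifier in the table is human, and the aligner, counter and annotation are not given in the sources used here. The table has 20263 genes, of which 3736 had no count in any library. Symbols and coordinates come from GENCODE 29 on GRCh38; 20148 identifiers had a symbol, 115 had none and 8 shared one, and 19722 are protein coding in that release. Counts that fall on near-identical genes (HSPA1A and HSPA1B, histones, ribosomal proteins, haemoglobins) depend on how the counter shares reads, which is unknown.

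Library totals were 31120459 and 29769568 for DMSO replicates 1 and 2, and 49924044 and 61605005 for 7A replicates 1 and 2, with 15545, 15533, 15119 and 15320 genes detected. The 7A mean is 1.83 times the DMSO mean. The floor is 3 counts, the upper 95% Poisson limit of the expected count where 0 is observed. It covers counting error alone and takes counts as independent. Of genes with 1 to 20 counts, 63.9%, 64.7%, 64.9% and 64.1% had an even count, as happens when both mates of a read pair are counted, so the counts are probably not independent fragments. The replicates of a group differed far beyond counting noise (chi-square per degree of freedom 37.9 for DMSO and 82.6 for 7A; 19.0 and 41.3 for counts divided by 2). The 20 best expressed genes held between 10.5% and 13.6% of each library.

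Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10), TMM scaling (factors 1.096 and 1.098 for DMSO, 0.926 and 0.897 for 7A), dispersion estimation and the quasi-likelihood F test, robust, with Benjamini-Hochberg adjustment over 14026 genes and a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of F. The biological coefficient of variation was 17.7%. Gene lists, 32 of them fixed before the data were examined, were tested with limma 3.58.1's camera at a preset correlation of 0.01, for lists with at least 3 tested members, adjusted over the lists. Each list is also reported by how many members passed over all genes and over the list alone. The lists are those named in the report. A further 8 lists, drawn up after the results were seen, appear in the closing section. Nothing states that the replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

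Named genes were set by a rule written before the data were examined: the 10 largest rises and falls among genes that passed with non-overlapping groups and a mean of at least 10 CPM over the 4 libraries, a fixed set of p53, apoptosis, ERBB and proliferation genes, and up to 4 members per list with the smallest adjusted p, at least 1 in each direction. Fits with so few counts that a fold has no meaning (TP53AIP1, ALAS2, FCER1G) are counted but not printed as folds. HBG2, the zinc finger family and the genes of the 8 later lists were chosen after their values were seen. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.

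Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 2 libraries, a replicate block, a test against a fold of 1.5, a threshold of 0.01, each library left out, and for the lists an estimated correlation and fry. Added after seeing the data were a per-library correction for GC, for length and for GC and length together (splines with 5 degrees of freedom on log2 CPM with a prior count of 2), counts divided by 2, thinning every library to 29769568 counts, a crossed pairing as a block, and library totals alone. The fit was tested on simulated data with the same depths, with 200 changed genes in each simulation of single genes. It called 7.5%, 47.8% and 84.8% of genes changed by a fold of 1.5, 2 and 4, always with the right sign. The shifted list was called, as were 0 of 99 unshifted lists. Genes were drawn independently there, so this does not test lists whose members vary together. With each gene's own dispersion, 130 of 589 calls over 5 simulations were false (22.1%), and with the trended dispersion 35 of 588 (6%). A simulated GC and length trend gave 3542 false calls before the correction and 25 after it. That trend was built on the same length and GC values that the correction uses. Transcript length means the length of a gene's annotated exons merged over its transcripts, which can exceed that of the transcript expressed. GC is that of the longest transcript. No genome sequence was used and reads were not analysed here.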

Results

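HCT116 colon cancer cells were given the compound 7A, which the series title calls a neratinib derivative, or DMSO for 24 h, and mRNA was sequenced from 2 libraries per group. The question is what 7A does to these cells, with p53 and apoptosis named in the title. Total counts were 31120459 and 29769568 in DMSO replicates 1 and 2, and 49924044 and 61605005 in 7A replicates 1 and 2. An observed count of 0 is compatible with an expected count of up to 3 at 95% confidence. That is 0.0964, 0.101, 0.0601 and 0.0487 counts per 1000000 (CPM) in the same order. This floor covers counting error alone and takes counts as independent. Values below are log2 fold changes of 7A over DMSO with their standard error, or mean CPM ± SD of 2 libraries scaled by TMM. A gene rose or fell when its adjusted p from edgeR was under 0.05.

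Among genes with a mean of at least 10 CPM over the 4 libraries, the largest rise was that of GADD45B and the largest fall that of ARRDC4. GADD45B (ENSG00000099860, chromosome 19, 2476122 to 2478259), a stress and growth-arrest gene, rose by 3.62 ± 0.27, from 43.5 ± 4.73 to 536 ± 179 CPM (edgeR adjusted p 0.000988). PPP1R15A (ENSG00000087074), which encodes the phosphatase subunit that reverses eIF2α phosphorylation, rose by 3.14 ± 0.18, from 125 to 1096 CPM. ARRDC4 (ENSG00000140450, chromosome 15, 97960698 to 97973838), an arrestin-domain gene that responds to glucose, fell by 5.59 ± 0.14, from 342 ± 7.06 to 7.11 ± 0.04 CPM (edgeR adjusted p 1.08e-05). FAT4, an atypical cadherin, fell by 3.78 ± 0.25, from 18.8 to 1.37 CPM.

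Of 14026 genes tested, 6795 (48.4%) changed: 3349 rose and 3446 fell. Without DMSO replicate 2, 3864 changed (1925 higher, 1939 lower), and without 7A replicate 2 there were 2208 lower. Changes of at least 2-fold were more often losses, with 997 genes higher and 1895 lower. The 2 groups overlapped for none of the 6795 genes. They did not overlap for 78.4% of all tested genes, against 33.3% by chance. The even balance depends on the scaling: 49.3% of changed genes were higher with TMM, but 28.3% with library totals alone, which moves the median of all genes from -0.03 to -0.29 and turns the p53, pro-apoptotic, unfolded protein, lysosome, intestinal differentiation and mesenchymal list medians negative. Upper-quartile scaling puts that median at -0.14 and turns only the intestinal differentiation list negative. The exact permutation p of 2 against 2 cannot go below 0.333, so each call leans on edgeR sharing the spread across genes. In 5 simulations built on these data, each with 200 changed genes, 130 of 589 calls (22.1%) were false where each gene had its own dispersion. Where dispersion followed the trend, 35 of 588 (6%) were false. Far more genes were called here (6795), and the false share depends on how many genes change, so these shares need not hold for them. Single calls near the threshold are the weakest.

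The other genes among the 10 largest rises were mixed. The histone gene H2BC21 rose by 3.45 ± 0.22 (5.73 to 62.5 CPM), the hair keratin-associated gene KRTAP2-3 by 3.07 ± 0.31 (3.13 to 26.3), the cytokine-signalling inhibitor SOCS1 by 3.04 ± 0.19 (3.15 to 25.9) and the nuclear import gene IPO4 by 3.04 ± 0.18 (8.57 to 70.3). The imprinted growth gene PHLDA2 rose from 194 to 1552 CPM, and the stress transcription factor ATF5 by 2.98 ± 0.19 (2.84 to 22.5). The heat shock chaperones HSPA1B and HSPA1A rose by 2.77 ± 0.16 and 2.73 ± 0.19; they are near-identical copies, so the split of reads between them is uncertain. Among the 10 largest falls were the zinc finger gene ZNF518B (-2.84 ± 0.25), the Golgi gene GOLGB1 (-2.84 ± 0.39), the membrane adaptor PAG1 (-2.83 ± 0.19), the clock gene PER2 (-2.75 ± 0.19), the histone demethylase KDM3A (-2.70 ± 0.30), the sestrin SESN3 (-2.69 ± 0.18) and ARID5B (-2.65 ± 0.21). CENPF, which encodes a kinetochore protein, fell by 3.09 ± 0.68 with uneven DMSO libraries (52.1 and 151 CPM, against 13.3 and 10.5 with 7A). The CENPF call was lost without 7A replicate 1 or 2 (edgeR adjusted p 0.126 and 0.145), and that of GOLGB1 without 7A replicate 2 (0.0592).

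**Figure D1:**
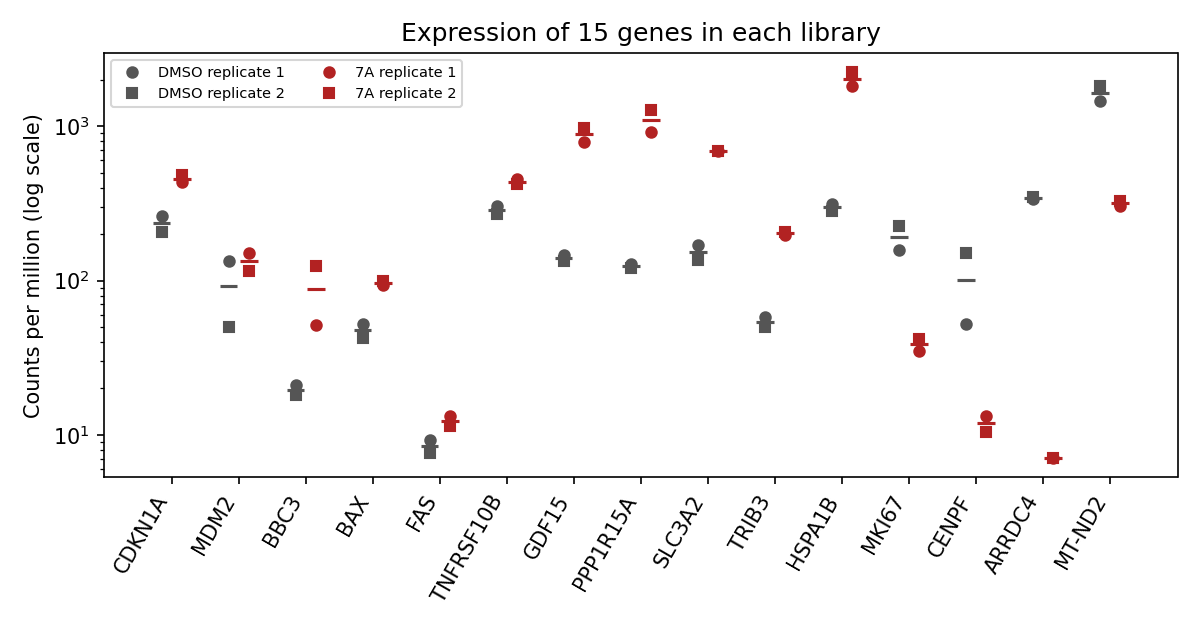
Expression (vertical axis, TMM-scaled CPM, log scale) of 15 genes in each of the 2 DMSO and 2 7A libraries (points), with group means as bars. CDKN1A goes from a mean of 235 to 458 CPM, ARRDC4 from 342 to 7.11, and the MDM2 points overlap between groups.

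Several death and arrest genes under p53 rose, but MDM2 did not pass. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), which encodes the cell-cycle inhibitor p21, rose by 0.96 ± 0.15, from 235 ± 40.6 to 458 ± 31.6 CPM (edgeR adjusted p 0.0026). The stress cytokine gene GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) rose by 2.66 ± 0.15, from 140 ± 9.58 to 886 ± 133 CPM. Of the killers, BAX rose by 1.02 ± 0.15 (47.5 to 96.7 CPM), BBC3, which encodes PUMA, by 2.16 ± 0.51, and the death receptors TNFRSF10B and FAS by 0.61 ± 0.12 (287 to 438 CPM) and 0.56 ± 0.19 (8.43 to 12.4 CPM). MDM2, which encodes the ligase that degrades p53, read 133 and 50.1 CPM with DMSO and 152 and 116 with 7A (0.55 ± 0.59; edgeR adjusted p 0.508); without DMSO replicate 1 it gave 1.43 (0.00633). The BBC3 call was lost without DMSO replicate 1 or 2 (edgeR adjusted p 0.141 and 0.2), and that of TNFRSF10B without DMSO replicate 2 (0.0606). FAS lost its call without DMSO replicate 1, DMSO replicate 2, 7A replicate 1 or 7A replicate 2 (edgeR adjusted p 0.0721, 0.248, 0.148, 0.0723).

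Of 48 p53 target genes tested, 21 rose and 8 fell (21 and 8 adjusted over the list alone). The arrest kinase gene PLK3 rose by 2.02 and the stress gene SESN2 by 1.72, while TP53INP1, an autophagy and death gene, fell by 1.18. The list median was 0.20, higher in camera (limma; adjusted p 0.0188), but -0.06 with library totals alone, with 12 genes higher and 15 lower. The list had adjusted p = 0.648 with an estimated correlation in limma's camera, and 0.0743 with fry. Of 30 pro-apoptotic genes, 13 rose and 2 fell (13 and 2 over the list alone), 6 of the listed genes being p53 targets too. TNFRSF1A, BID and PMAIP1, which encodes NOXA, rose by 1.21, 1.29 and 1.20, and the death adaptor gene FADD fell by 0.95. The pro-apoptotic median was 0.19 (-0.08 with library totals alone), with a camera adjusted p of 0.0467 that became 0.0985 without DMSO replicate 2, 0.101 without 7A replicate 1 and 0.0715 without 7A replicate 2. The same list had adjusted p = 0.402 with an estimated correlation in limma's camera. Of 13 anti-apoptotic genes, 4 rose and 2 fell (5 and 2 over the list alone), median 0.61, and the list did not pass (camera adjusted p 0.233). The caspase inhibitor AVEN rose by 2.23 and BCL2L1, which encodes BCL-XL, by 1.28 (218 to 527 CPM), while the inhibitor-of-apoptosis genes BIRC2 and BIRC6 fell by 1.18 and 1.59. BIRC6 lost its call without 7A replicate 1 or 2 (edgeR adjusted p 0.0513 and 0.0675).

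The ATF4 arm of the stress response was the list with the smallest p. Of 38 ATF4 and integrated stress response genes, 28 rose and 1 fell (30 and 1 over the list alone), with a median of 0.97 (camera adjusted p 2.46e-12, and adjusted p = 0.378 with an estimated correlation). The amino acid transporter gene SLC3A2 rose by 2.17 (153 to 689 CPM), the pseudokinase gene TRIB3 by 1.90 (54.1 to 202 CPM), and the folate enzyme gene ALDH1L2 fell by 2.34. Of 22 heat shock genes, 14 rose and 1 fell (14 and 1 over the list alone), median 0.69 (camera adjusted p 3.67e-08, and adjusted p = 0.376 with an estimated correlation). HSPE1, a mitochondrial chaperone gene, rose by 1.53, while HSPA4L fell by 0.67, a call lost without DMSO replicate 2 (edgeR adjusted p 0.148) and without 7A replicate 2 (0.118). Of 28 NRF2 targets, 15 rose and 4 fell (16 and 4 over the list alone), median 0.50 (camera adjusted p 0.00429, and adjusted p = 0.378 with an estimated correlation). The haem oxygenase gene HMOX1 rose by 1.74 (19.5 to 65.3 CPM), thioredoxin TXN by 1.02, and OSGIN1 fell by 0.98. Of 24 endoplasmic reticulum and unfolded protein genes, 9 rose and 4 fell (11 and 4 over the list alone), and the list did not pass (median 0.24, -0.02 with library totals alone; camera adjusted p 0.217). The chaperone genes DNAJB11, HYOU1 and CRELD2 rose by 0.93, 0.92 and 0.78, and the degradation gene SEL1L fell by 1.45.

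Replication genes rose while mitotic genes split. Of 55 DNA replication and S phase genes, 30 rose and 2 fell (30 and 2 over the list alone), median 0.50 (camera adjusted p 9.25e-06, and adjusted p = 0.378 with an estimated correlation). The helicase genes MCM5 and MCM2 rose by 1.73 (48.4 to 161 CPM) and 1.39, and the S phase activator E2F1 by 1.75. The clamp loader gene RFC1 fell by 1.28, a call lost without 7A replicate 2 (edgeR adjusted p 0.102). Of 55 G2/M and mitosis genes, 14 rose and 18 fell (15 and 20 over the list alone), median -0.06 (camera adjusted p 0.61; 0.0301, lower, without DMSO replicate 1). The ubiquitin-conjugating enzyme gene UBE2C rose by 1.30 (105 to 258 CPM) and the kinase gene CDK1 by 1.04 (99.6 to 205). In contrast, the proliferation marker MKI67 fell by 2.32 ± 0.21 (193 to 38.6 CPM) and the kinesin gene KIF20A by 1.57. The cyclin gene CCND1 rose by 1.06 ± 0.14, from 398 to 832 CPM. Of 26 replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, 13 rose and 2 fell (14 and 4 over the list alone), median 1.16 (camera adjusted p 9.21e-05, and adjusted p = 0.399 with an estimated correlation). H3C10 and H2BC11 rose by 3.30 and 2.49; H3C6 fell by 1.33, a call lost without DMSO replicate 2, 7A replicate 1 or 7A replicate 2 (edgeR adjusted p 0.0896, 0.0513, 0.0686). Of 31 homologous recombination and Fanconi genes, 7 rose and 7 fell (7 and 7 over the list alone); the median of -0.03 and mean of -0.05 were negative while camera ranked the list higher (adjusted p 0.813). FANCA, RAD54L and UBE2T rose by 1.06, 0.93 and 0.83, and the damage kinase gene ATM fell by 1.20.

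Among the ERBB receptors, EGFR fell by 0.63 ± 0.12 (247 to 159 CPM; edgeR adjusted p 0.00458) and ERBB3 by 0.70 ± 0.19, while ERBB2 rose by 0.77 ± 0.15 (70.8 to 121 CPM). The EGFR fall is not separable from transcript length, since a correction for GC and length gave 0.02 (edgeR adjusted p 0.859). For its part, ERBB3 lost its call without DMSO replicate 1 (0.116) and without 7A replicate 1 (0.0771). Of 21 ERBB receptor, ligand and feedback genes, 7 rose and 7 fell (7 and 7 over the list alone); the median of -0.43 and mean of -0.03 were negative while camera ranked the list higher (adjusted p 0.61). After the correction for GC and length 9 of them were higher and 2 lower, median 0.02 (camera adjusted p 0.185). The ligand genes HBEGF and BTC rose by 1.98 and 1.42, and the adaptor gene GRB7 by 1.22. Of 31 ERK output genes, 14 rose and 5 fell (14 and 5 over the list alone), median 0.64 (camera adjusted p 7.09e-05, and adjusted p = 0.446 with an estimated correlation). The ERK phosphatase gene DUSP5 rose by 1.74 (451 to 1510 CPM), KLF6 by 1.45 and JUN by 1.69, whereas the inhibitor SPRED1 fell by 0.80. DUSP6, another ERK phosphatase gene, held at 378 and 394 CPM (0.06 ± 0.12; edgeR adjusted p 0.694). MYC did not pass (14.2 and 14.1 CPM; -0.01 ± 0.42; edgeR adjusted p 0.991), and its 7A libraries differed, at 19.5 and 8.78 CPM. Of 21 FOXO targets, 5 rose and 11 fell (5 and 12 over the list alone), but the list did not pass in camera (median -0.57; adjusted p 0.19), while limma's fry called it lower (adjusted p 0.0325). GADD45A rose by 1.24 and the receptor gene IGF1R fell by 1.12.

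Genes for making lipids and ribosomes rose. Of 25 sterol synthesis and uptake genes, 21 rose and 0 fell (21 and 0 over the list alone), median 0.72 (camera adjusted p 2.49e-08, and adjusted p = 0.399 with an estimated correlation): ACAT2 by 1.47, DHCR7 by 1.18 and FDPS by 1.16. Of 17 fatty acid synthesis genes, 13 rose and 1 fell (13 and 1 over the list alone), median 0.60 (camera adjusted p 0.000215, and adjusted p = 0.378 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, rose by 1.17, ME1 by 1.25 and FADS1 by 1.04; ACSL1 fell by 0.73, a call lost without DMSO replicate 2 (edgeR adjusted p 0.0628). Of 47 ribosome biogenesis and MYC target genes, 30 rose and 0 fell (30 and 0 over the list alone), median 0.64 (camera adjusted p 5.12e-10, and adjusted p = 0.376 with an estimated correlation). The polyamine gene SRM rose by 2.61 (26.7 to 163 CPM), MYBBP1A by 2.41, BOP1 by 1.74 and MRTO4 by 1.73. Of 76 cytosolic ribosomal protein genes, which have many processed copies in the genome, 54 rose and 1 fell (56 and 1 over the list alone), median 0.51 (camera adjusted p 5.79e-08, and adjusted p = 0.399 with an estimated correlation). These transcripts are short, and a correction for transcript length alone took the list to a camera adjusted p of 0.0641. With the correction for GC and length together it was still called higher (camera adjusted p 0.0102), with a median of 0.18, 20 genes higher and 2 lower. The counts also depend on the scaling. With the upper quartile 37 members were higher and 1 lower. With library totals alone 12 were higher and 2 lower, median 0.24. RPL35, RPL35A and RPL36 rose by 0.94, 0.71 and 0.74; RPL23A fell by 0.67, a call lost without DMSO replicate 2, 7A replicate 1 or 7A replicate 2 (edgeR adjusted p 0.174, 0.131, 0.214).

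Mitochondrial and nuclear genes of the respiratory chain went opposite ways. Of 13 mitochondrially encoded genes, 12 fell and 0 rose (12 and 0 over the list alone), median -1.38 (camera adjusted p 6.58e-11, and adjusted p = 0.399 with an estimated correlation). MT-ND2 fell by 2.37 (1640 to 317 CPM), MT-ND1 by 1.84, MT-ND6 by 1.57 and MT-ND3 by 1.38. Mitochondrial counts made up 6.59% and 7.73% of the DMSO libraries and 3.05% and 4.07% of the 7A libraries. Of 51 nuclear respiratory chain genes, 32 rose and 0 fell (37 and 0 over the list alone), median 0.53 (camera adjusted p 5.89e-07, and adjusted p = 0.399 with an estimated correlation). ATP5MC1 rose by 1.38, NDUFB10 by 1.28, CYC1 by 1.23 (228 to 534 CPM) and NDUFB8 by 1.02. After the correction for GC and length these became 0.965, 0.597, 0.586 and 0.458. The list then had 20 genes higher and 1 lower, median 0.39 (camera adjusted p 0.00224). Of 36 hypoxia and glycolysis genes, 6 rose and 17 fell (8 and 17 over the list alone), median -0.37 (camera adjusted p 0.0327, and adjusted p = 0.691 with an estimated correlation). The hypoxia list was lost without DMSO replicate 1 (camera adjusted p 0.0899), without 7A replicate 1 (0.101) and with limma's fry (0.0774). The enolase gene ENO2 fell by 1.34 and the collagen hydroxylase gene P4HA1 by 1.92, while the secreted factors VEGFA and ADM rose by 1.23 and 1.35. Of 41 lysosome and autophagy genes, 9 rose and 5 fell (4 and 3 over the list alone), and the list did not pass (median 0.19, camera adjusted p 0.544). With library totals alone its median was -0.08, with 2 genes higher and 11 lower. Upper-quartile scaling gave 4 higher and 6 lower. The protease gene CTSZ rose by 0.85; FLCN, the proton pump gene ATP6V1B2 and FNIP1 fell by 1.54, 0.86 and 0.90.

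**Figure D2:**
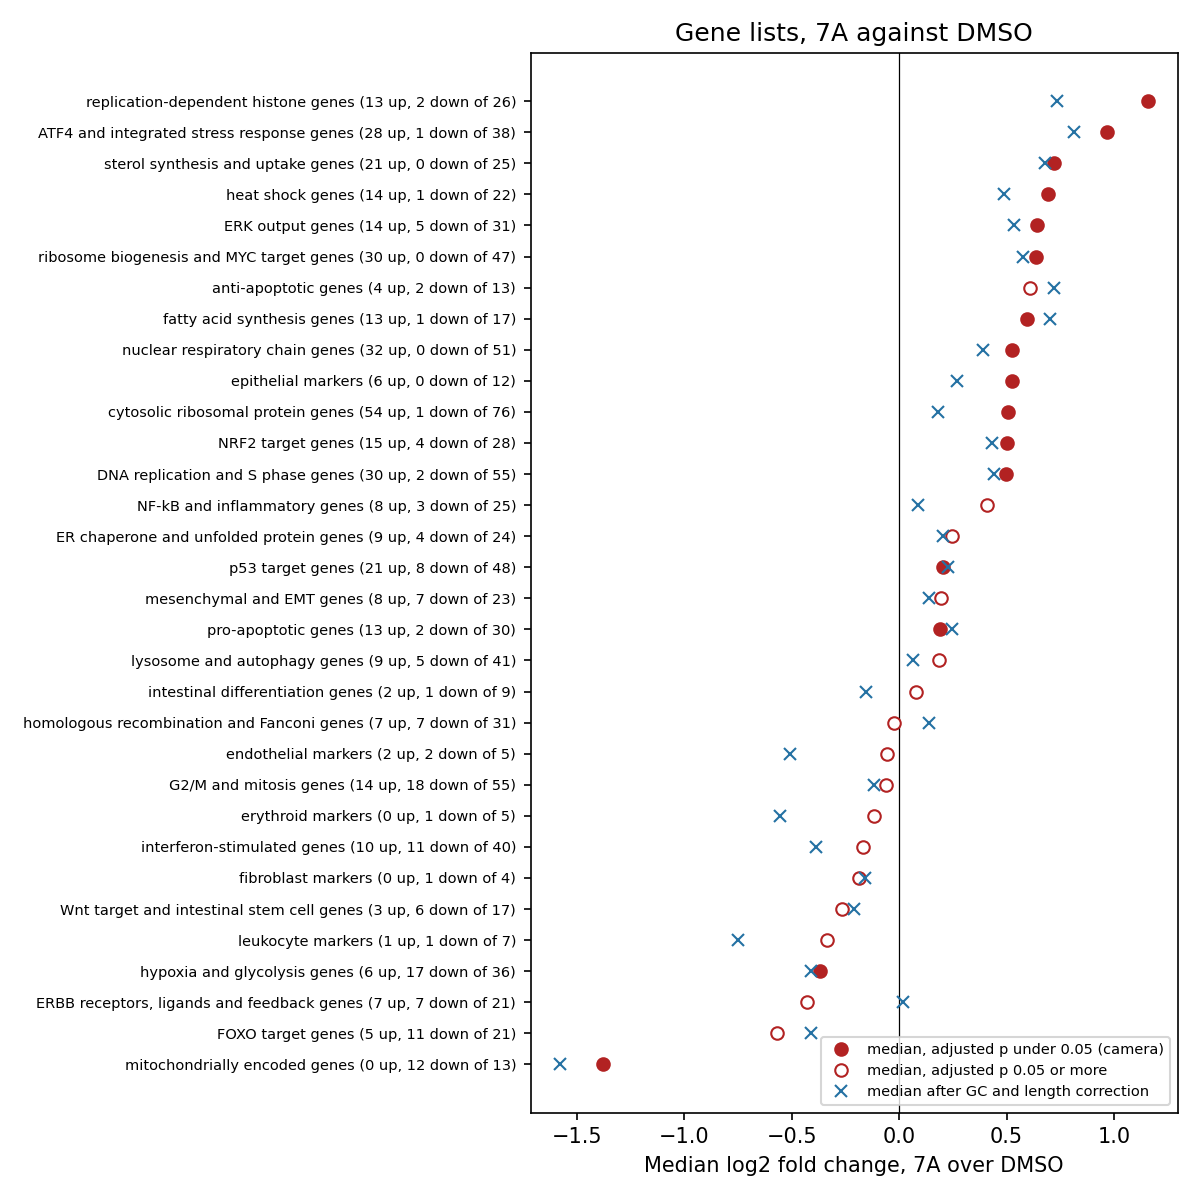
Median log2 fold change of 7A over DMSO (horizontal axis) for each of 32 gene lists (vertical axis); points are filled where the camera adjusted p was under 0.05, and crosses are medians after a correction for GC and transcript length. ATF4 targets (0.97) and mitochondrially encoded genes (-1.38) lie far apart. Points and crosses use TMM scaling, and medians with library totals alone are not drawn. With library totals alone the p53 (-0.06), pro-apoptotic (-0.08), unfolded protein (-0.02), lysosome (-0.08), intestinal differentiation (-0.19) and mesenchymal (-0.07) medians turn negative.

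Inflammatory, interferon and lineage lists mostly stayed unshifted. Of 25 NF-kB and inflammatory genes, 8 rose and 3 fell (8 and 3 over the list alone), median 0.41 (camera adjusted p 0.207): NFKB1 rose by 1.20, IL18 by 1.04 and CXCL8 by 1.01, and REL fell by 1.89. Of 40 interferon-stimulated genes, 10 rose and 11 fell (11 and 14 over the list alone), median -0.17 (camera adjusted p 0.578). With upper-quartile scaling 7 were higher and 16 lower, and with library totals alone 3 and 19. IRF1 rose by 0.95 (43.0 to 83.2 CPM) and IFI35 from 11.9 to 23.8 CPM, while IFIT2 and IFIT3 fell by 1.38 and 1.58. Of 17 Wnt target and intestinal stem cell genes, 3 rose and 6 fell (3 and 6 over the list alone), median -0.27 (camera adjusted p 0.548), with SOX9 up by 1.15 and EPHB3 and NKD1 down by 1.33 and 1.03. Of 9 intestinal differentiation genes, 2 rose and 1 fell (1 and 1 over the list alone; median 0.08, -0.19 with library totals alone and -0.03 with the upper quartile; camera adjusted p 0.61). KLF4 rose by 0.70, and KRT20 rose from 0.122 to 0.995 CPM, near the floor, a call lost without 7A replicate 1 or 2 (edgeR adjusted p 0.162 and 0.144). FCGBP, a mucus gene, fell by 0.88, a call lost without DMSO replicate 1 (edgeR adjusted p 0.076) and without 7A replicate 1 (0.063). Of 23 mesenchymal genes, 8 rose and 7 fell (10 and 7 over the list alone; median 0.20, -0.07 with library totals alone; camera adjusted p 0.19): CCN1 rose by 2.57 and LAMB3 by 0.94, and THBS1 fell by 0.87. Of 12 epithelial markers, 6 rose and 0 fell (6 and 1 over the list alone), median 0.53 (camera adjusted p 0.0327, 0.0627 without 7A replicate 2, 0.0526 with limma's fry; adjusted p = 0.648 with an estimated correlation): KRT8 by 1.14 (1660 to 3668 CPM), KRT18 by 1.09 and CLDN7 by 1.03.

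Markers of other cell types did not pass as lists. Of 4 fibroblast markers, 0 rose and 1 fell (0 and 1 over the list alone), median -0.19 (camera adjusted p 0.689): COL1A1, by 0.64 (56.2 to 36.1 CPM), a call lost without DMSO replicate 1 or 2 (edgeR adjusted p 0.0717 and 0.0501). Of 7 leukocyte markers, 1 rose and 1 fell (1 and 0 over the list alone), median -0.33 (camera adjusted p 0.61), with CD68, a lysosomal gene, up by 1.11 (34.0 to 73.6 CPM) but not without DMSO replicate 2 (edgeR adjusted p 0.0623). FCER1G fell from 0.416 to 0.0453 CPM, at the floor, but not without DMSO replicate 2 (edgeR adjusted p 0.0566) or 7A replicate 1 (0.127). Of 5 endothelial markers, 2 rose and 2 fell (2 and 2 over the list alone), median -0.06 (camera adjusted p 0.923): EGFL7 rose by 0.54 (83.2 to 121 CPM), a call lost without DMSO replicate 2 (edgeR adjusted p 0.112) and without 7A replicate 2 (0.0568). ROBO4 (0.509 to 1.61 CPM) also rose, and KDR (0.527 to 0.0885 CPM) and VWF (0.776 to 0.206 CPM) fell. These low calls were lost without 7A replicate 2 for ROBO4 (edgeR adjusted p 0.0506), without DMSO replicate 2, 7A replicate 1 or 7A replicate 2 for KDR (0.106, 0.0713, 0.0763), and without DMSO replicate 1, 7A replicate 1 or 7A replicate 2 for VWF (0.111, 0.0772, 0.0729). Of 5 erythroid markers, 0 rose and 1 fell (0 and 1 over the list alone), median -0.12 (camera adjusted p 0.61). ALAS2 fell from 0.255 to 0.0091 CPM, below the floor, and the best expressed, HBG2, read 10.6 CPM with DMSO and 9.74 with 7A.

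Longer transcripts, by the merged annotated exons of each gene, tended to be lower with 7A. The Spearman correlation of log2 fold change with transcript length was -0.344 over 14011 genes, and the median went from 0.46 in the shortest 10% of genes to -0.65 in the longest 10%. In the G2/M list the 14 genes that rose had a median transcript length of 2094 and the 18 that fell 4440.5, but after a correction of each library for GC and length the list still split, 10 higher and 19 lower. MKI67 (-1.63), KIF20A (-1.59), UBE2C (0.86) and CDK1 (0.87) were still called. Zinc finger genes with ZNF symbols, looked at after their values were seen, were mostly low: of 392 tested, 29 rose and 199 fell, median -0.78, and after the correction 29 rose and 183 fell, median -0.59. A trend also runs within the groups, at 0.174 between the DMSO libraries and -0.209 between the 7A libraries, so library preparation may contribute. Given genomic span and GC, the partial rank correlations with length were 0.012 and -0.07, against -0.224 for 7A over DMSO. With GC itself the Spearman correlations were -0.347 and 0.431 between replicates and 0.241 for 7A over DMSO. After the correction for GC and length, 6602 genes passed, 5028 of them (74% of the 6795) with the same sign and 4 with the opposite one. Among named genes that correction took the call but left most of the fold of BBC3 (1.70, edgeR adjusted p 0.0547) and KRT20 (2.81, 0.053). Calls also went, with smaller folds, for ERBB3 (-0.41, edgeR adjusted p 0.0863), ATM (-0.24, 0.127), SPRED1 (-0.26, 0.135), CRELD2 (0.27, 0.0687), CTSZ (0.26, 0.0604) and RPL35 (0.26, 0.0668). The same held for RPL36 (0.13, edgeR adjusted p 0.494), NKD1 (-0.33, 0.0512), THBS1 (-0.35, 0.0803), EGFL7 (0.17, 0.194) and HSPA4L (0.03, 0.837). It left the p53 list called (camera adjusted p 0.0197), with a median of 0.23, 15 genes higher and 9 lower. The pro-apoptotic list was not called (0.216), though its median was 0.25 with 11 genes higher and 5 lower, and neither was the epithelial list (camera adjusted p 0.203; median 0.27, 5 higher and 2 lower). The anti-apoptotic list passed only then, higher (camera adjusted p 0.0416), with a median of 0.72, 6 genes higher and 2 lower. In the uncorrected fit it had a camera adjusted p of 0.691 with an estimated correlation. Uncalled lists also moved with the correction: homologous recombination and Fanconi genes went to 11 higher and 3 lower (median 0.14), interferon-stimulated genes to 4 and 13 (-0.39), NF-kB genes to 4 and 4 (0.09), and the intestinal differentiation median to -0.15.

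**Figure D3:**
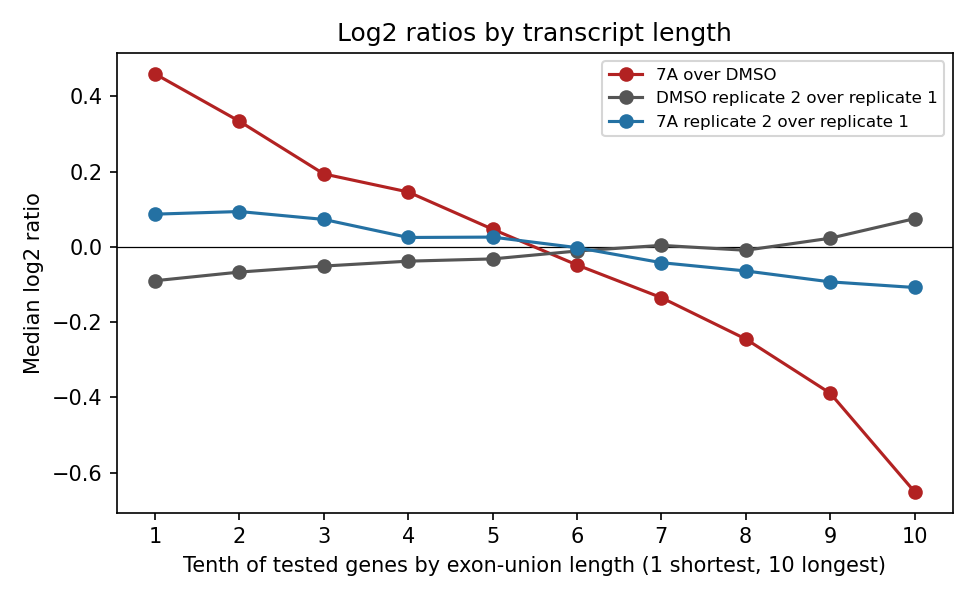
Median log2 ratio (vertical axis) in 10 equal groups of the tested genes by transcript length (horizontal axis, 1 shortest), for 7A over DMSO and for replicate 2 over replicate 1 within each group. The 7A over DMSO line goes from 0.46 to -0.65, while the DMSO pair goes from -0.09 to 0.08 and the 7A pair from 0.09 to -0.11.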

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

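The GC, length, counts divided by 2, thinning, crossed pairing and library totals settings were chosen only after the results were seen; the others were set before the data were examined. Of 143 named genes, 140 passed in the main setting; DESeq2 kept the direction and side of the threshold for 140 of the 143, voom for 142 and RLE for 142. The count of changed genes was 6897 with DESeq2, 6738 with voom, 6839 with RLE and 6840 with the upper quartile. A filter of 5 CPM in 2 libraries left 1248 genes lower by at least 2-fold, having fewer genes to test. Testing against a fold of 1.5 left 2589 (1129 higher, 1460 lower), and a threshold of 0.01 left 3860 (2049 higher, 1811 lower), both stricter by construction. With library totals alone 1951 genes were higher, 476 of them by at least 2-fold; that setting drops the composition factor. With an estimated inter-gene correlation 0 lists passed (0 higher, 0 lower); the cause was not tested. Leave-one-out, where the lone sample is assumed to vary like the others, gave 3864 to 5673 changed genes (1925 to 3054 higher, 1939 to 2619 lower) and 1 to 2 lists lower.

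Directions turned as follows, and the cause was not tested. For lists, a leave-one-out range covers every library left out, including fits that kept the main direction. G2/M and mitosis genes turned leave-one-out only without 7A replicate 2. Without DMSO replicate 1, the low end of their range, they stayed lower. MYC, -0.007 in the main setting: 0.004 with DESeq2, 0.003 with RLE, 0.008 without a filter, 0.024 thinned. Leave-one-out it turned only without DMSO replicate 1 (0.212) and without 7A replicate 2 (0.454), over a range from -0.667 to 0.454. DUSP6: -0.052 with the upper quartile, -0.025 with the 5 CPM filter, -0.209 with library totals alone. EGFR: 0.019 with the length and 0.020 with the GC and length correction; HSPA4L: 0.034 with the latter. Lists, as camera adjusted p in limma: homologous recombination and Fanconi genes 0.873 with the 5 CPM filter, 0.974 with the crossed pairing, 0.474 to 0.866 leave-one-out; intestinal differentiation genes 0.845 with the 5 CPM filter; G2/M and mitosis genes 0.918 with the GC correction, 0.0301 to 0.918 leave-one-out; fibroblast markers 0.891 with the length correction; leukocyte markers 0.658 with counts divided by 2, 0.47 to 0.961 leave-one-out; endothelial markers 0.658 with counts divided by 2, 0.944 with library totals alone, 0.84 to 0.986 leave-one-out; erythroid markers 0.918 to 0.986 leave-one-out.

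Whether equal replicate numbers pair the samples is not known; the replicate differences of the 2 groups had Pearson -0.05 and Spearman -0.209. With a replicate block 6216 genes passed, 6027 of them main calls with the same sign (88.7% of the 6795); of the named genes and fixed lists only CENPF, FAS and the pro-apoptotic list lost their calls (list camera adjusted p 0.0623), and with the crossed pairing 7752 passed. The pro-apoptotic list, near the threshold, was also lost with the 5 CPM filter (camera adjusted p 0.099), the GC correction (0.0623), the length correction (0.228), counts divided by 2 (0.0598), thinning (0.0509) and library totals alone (0.0512); the epithelial list was lost with the 5 CPM filter (0.142), the GC correction (0.124) and the length correction (0.123). After thinning 6612 genes passed, and 6455 of these (95% of the 6795) were main calls with the same sign. Depth limits genes at the floor, such as ALAS2 and FCER1G.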

Other observations

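The lists in this paragraph and the next, and the p53 and mitochondrial tests marked so below, were chosen only after the results were seen, so list p-values here describe genes partly picked for their change. Genes of the actin cytoskeleton under SRF rose together: 22 of 28 rose and 0 fell (22 and 0 over the list alone), median 0.76 (limma camera adjusted p 4.97e-10; adjusted p = 0.194 with an estimated correlation). ACTB rose by 2.23 (1205 to 5665 CPM), ACTG1 by 1.66 and the myosin gene MYL9 by 2.14. Of 31 proteasome genes, 22 rose and 0 fell (22 and 0 over the list alone; median 0.61; camera adjusted p 8.89e-06; adjusted p = 0.194 with an estimated correlation), with PSMB2 up by 1.33 and PSMA1 by 1.03. After the GC and length correction the proteasome list had 14 genes higher, 0 lower and a median of 0.28 (camera adjusted p 0.00333). GADD45 and stress phosphatase genes rose in 6 of 9 cases and fell in 1 (6 and 1 over the list alone; median 1.24), among them DUSP1 by 2.20 and DUSP2 by 2.59. That list was drawn up around GADD45B and PPP1R15A, so no test is given for it.

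Of 5 glucose-responsive MondoA targets, listed because ARRDC4 had the largest fall and so given without a test, 3 fell and 0 rose (3 and 0 over the list alone; median -0.47). Beside ARRDC4, KLF10 fell by 1.29 and PFKFB4 by 0.47, while HK2 and PFKFB3 did not pass. Of 18 circadian genes, 5 rose and 6 fell (5 and 8 over the list alone; median -0.53; camera adjusted p 0.384): PER2, CRY1 and CRY2 fell by 2.75, 2.08 and 1.97, while NR1D1 rose by 2.47 (177 to 979 CPM) and BHLHE40 by 1.53. Of 13 YAP targets, 6 rose and 3 fell (6 and 3 over the list alone; median 0.25, -0.01 with library totals alone; camera adjusted p 0.0281; adjusted p = 0.337 with an estimated correlation). Of 32 histone methyl- and acetyltransferase genes, 6 rose and 15 fell (7 and 15 over the list alone; median -0.38; camera adjusted p 0.0281; adjusted p = 0.337 with an estimated correlation), with KAT6A down by 2.63 and ASH1L by 1.70; after the GC and length correction that list did not pass (0.843) and its median was 0.06. Of 12 tubulin genes, 2 rose and 3 fell (2 and 3 over the list alone; median 0.33; camera adjusted p 0.87), and after that correction the tubulin list turned lower without passing (median -0.24, 2 higher and 4 lower; camera adjusted p 0.069).

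Why log2 fold change falls with transcript length was weighed 3 ways. If bias that follows annotated length and GC made all of the calls, few should outlive a per-library correction. Yet 74% kept their call and sign. Bias that varies between genes of like length and GC would outlive the correction, so it is not excluded. The 74% bears on the calls and not on the trend, which the correction removes by its design. Library depth was not settled by thinning, since thinning keeps each gene's expected share of its library. After thinning to the smallest library the Spearman correlation was still -0.351. That shows only that unequal totals in the fit do not make the trend. Distance transcribed adds little: the partial rank correlation with genomic span, given transcript length and GC, was -0.053. A trend with length also runs between replicates, but given span and GC its partial rank correlation was 0.012 (DMSO) and -0.07 (7A). For 7A over DMSO it was -0.224. The replicate differences followed GC more, with partial rank correlations of -0.277 (DMSO) and 0.377 (7A), against 0.131 for 7A over DMSO. A technical share of the trend, partial or whole, stays open.

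Mitochondrially encoded transcripts fell while nuclear respiratory chain transcripts did not. The GC and length correction was no real test of bias here, since it could hardly have raised the mitochondrial median. These transcripts are short (list median 784), and the shortest tested genes tended to rise (median 0.46). The length trend thus runs against this fall, and after correction the mitochondrial median was -1.58. Scaling does not account for the opposite shifts, in a test written after the mitochondrial shares had been seen. The ratio of mitochondrial to nuclear chain counts needs no scaling. It was 9.62 and 11.9 with DMSO and 3.69 and 5.01 with 7A. The lowest DMSO ratio was 1.92 times the highest 7A ratio. What lowers the transcripts was not tested.

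The p53 target list might be carried by 7 members that ATF4 or CHOP also induce (SESN2, ATF3, GDF15, TNFRSF10B, BBC3, PMAIP1, GADD45A), a test written after some of their values had been seen. All 7 rose, with a median of 1.72, and without them the median was 0.01 and the unadjusted camera p (limma) was 0.333. The test cannot tell, since leaving out 7 random members of the 21 that rose also gave a p of at least 0.05 in 97.5% of 1000 draws, though a p as large as 0.333 in only 2.4%. Leaving out 7 random members of all 48 gave a p of at least 0.05 in 8.6% of draws and one as large as 0.333 in 0%, but the 7 genes had all risen. After the correction for GC and length the unadjusted camera p of the whole list was 0.00862 (limma). An average trend with annotated length and GC thus does not make the shift, but bias scattered around it is not excluded. Without the 7 genes the corrected list had a median of 0.07 and an unadjusted camera p of 0.298 (limma).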
